A study of Homo sapiens with 12 samples.

How the data were processed

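Polyadenylated RNA from Daoy cells, an established human medulloblastoma line, was sequenced in 12 libraries: 4 of the parental line, 4 of clone D3 and 4 of clone E4. The values are read counts per gene in 1 table of all 12 libraries, as the authors deposited them, with no normalization. They were whole numbers, and the sums per library ran from 23761733 to 31871873. Per the submitters' processing notes the tools were Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and DESeq2 on GRCh38. Their roles and order, the annotation release and the strand setting were not given in the sources used here. Counts of overlapping or antisense genes, and of families whose members share sequence, are therefore uncertain. Of the 57500 entries of the table, 56898 had a gene identifier in GENCODE 29, from which positions and gene types were taken, and 485 had no gene name in the table.

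Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups (minimum count 10, minimum total count 15), which left 19270 genes holding at least 99.86% of the counts of each library. Libraries were scaled by TMM, whose factors ran from 0.9519 to 1.047. All 12 libraries were fitted together with a term for each of the 3 groups, giving 9 residual degrees of freedom and a median biological coefficient of variation of 6.88%. Each clone was compared with the parental line, and clone E4 with clone D3, by the two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over the 19270 genes. A gene was called at an adjusted p under 0.05. Levels are TMM-scaled CPM (as computed by edgeR from the library totals) as mean ± SD over 4 libraries. The standard error of a log2 fold change was derived from the test, as its absolute value over the square root of the F statistic. The labels name 4 collections of each line, and nothing in them says that these were separate cultures, so p-values measure the spread between these libraries only. A pairwise chi-square comparison of counts found no libraries that agreed within sampling noise.

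The tests, the alternatives, 37 gene lists and the rule for named genes were fixed before the data were examined. The lists held 1182 symbols, of which 1181 were matched to the table. The 36 lists with at least 5 tested members were tested with camera (limma 3.58.1; preset correlation between genes 0.01, two-sided), adjusted over the 36 lists within each comparison. Camera asks whether a list moved differently from the other genes. The same test with a correlation estimated for each list, and fry, which asks whether a list moved at all, were run beside it. For each list the calls were also counted with p-values adjusted over the list alone.

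The named genes were GNPTAB; the 5 largest rises and 5 largest falls of each clone among called protein-coding genes with a mean of at least 5 CPM and group ranges that did not overlap; under the same conditions, the 8 rises and 8 falls with the largest smaller change of both clones, and the 4 genes in each direction that moved oppositely; and in each list up to 4 members, the 2 highest and 2 lowest by mean change among members called in both clones in the same direction. Some genes that the rule names are not reported here. Any member could be named in the list of mannose 6-phosphate tagging and in markers of other cell types.

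Both clones were compared with the same parental libraries, which ties their fold changes together. The overlap and the correlation of the clones were therefore set beside 20 simulated sets in which neither clone differed from the parental line, and beside the 6 ways of giving 2 parental libraries to each clone. Genes were also grouped in bins of 10 Mb, whose medians were compared with 10000 random gene sets of the same size. A bin was shifted if its median lay outside the 0.5 to 99.5 percentile range. A scan for the stretch of each chromosome that differed most from the rest of it used genes with a mean of at least 5 CPM, stretches of at least 20 genes and 1000 shuffles of gene order. The guide sequence in the labels was searched in the annotated transcripts and placed on the genome.

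The procedure was tested on simulated data with 200 changed genes. It recovered 44.9%, 66.0%, 84.0% and 98.0% of changes of 1.25, 1.5, 2 and 4-fold in the simulation of clone D3, and 36.0%, 59.2%, 78.0% and 100% in that of clone E4. False calls were 22 of 193 (11.4%) and 12 of 172 (6.98%). A list with a planted change ranked 1 of the lists in both, and the number of other lists called was 0 for clone D3 and 2 for clone E4.

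The alternatives were median-of-ratios size factors, library size alone, no filter beyond 1 count, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a block for replicate number, a test against changes of up to 1.5-fold (glmTreat), and leaving out each library in turn. Added after the data were seen were the removal of genes that stood apart in replicate 3 of clone D3, and the 10 Mb bin medians as an offset. The part of each gene's CPM that follows BPIFA1 and BPIFB1 from library to library was also fitted after the data were seen, by least squares with 1 level per line and a slope for each of these genes, and calls were adjusted over the fallen members of each list. Genes outside the named rule that were picked later are said to be so where they appear.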

Results

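Expression was measured by sequencing of polyadenylated RNA from Daoy cells and from 2 clones of them in which GNPTAB had been targeted with a guide RNA, 4 libraries each. GNPTAB encodes the catalytic subunits of the enzyme that starts the mannose 6-phosphate tag, by which soluble enzymes are sorted to lysosomes. Its loss causes the lysosomal storage disease mucolipidosis II, and the series uses the clones as a neuronal cell model of it, with an interest in neurodegeneration and drug metabolism. Per the labels, clone D3 carried alleles with 2, 2 and 1 bases deleted, and clone E4 alleles with 1 base deleted and 1 inserted. The totals were 23761733 to 29592138 counts in the parental libraries, 25944897 to 29343012 in clone D3 and 27274388 to 31871873 in clone E4.

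Libraries of the same line were close to each other, with Pearson correlations of log2 expression across genes of 0.993 to 0.998, against 0.956 to 0.971 between lines; genes are not independent replicates. In replicate 3 of clone D3, 175 genes lay below and 4 above the other libraries of that clone, while no other library stood apart in more than 5 genes. Markers of airway epithelium were among the 175 and are given with the gene groups they moved with. Each knockout is represented by 1 clone, so a difference from the parental line belongs to that clone.

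GNPTAB itself (ENSG00000111670; GRCh38 chromosome 12, 101745497 to 101830938, minus strand) fell in both clones. Its level was 81.2 ± 3.96 CPM (SD, n = 4) in the parental line, 30.4 ± 0.918 CPM in clone D3 and 14.9 ± 0.731 CPM in clone E4. The log2 fold change was -1.42 ± 0.05 (SE) in clone D3, which is 0.374-fold (edgeR adjusted p = 3.63e-17), and -2.44 ± 0.05 in clone E4, which is 0.184-fold (adjusted p = 7.03e-21). Clone E4 was lower than clone D3 by a log2 difference of -1.02 ± 0.05 (adjusted p = 1.6e-13). The guide CACGTAGAGCCCATACCTGT matched 5 transcripts of GNPTAB on the opposite strand and none of another gene. It lies at 101830610 to 101830629 in exon 1 of the 21 exons of transcript GNPTAB-201, within the coding sequence, beside a GGG motif. By this match, cleavage falls between coding positions 49 and 50 of 3768. The labels number the edited bases on a reference that they do not name, and those numbers do not match these coding positions. Nearly all of GNPTAB lies on the centromere side of the guide's target site. Scanned genes within 10 Mb on that side had a median log2 fold change of -0.51 in clone E4 and -0.12 in clone D3. How much of the lower GNPTAB level in clone E4 follows this regional fall was not tested.

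**Figure D1:**
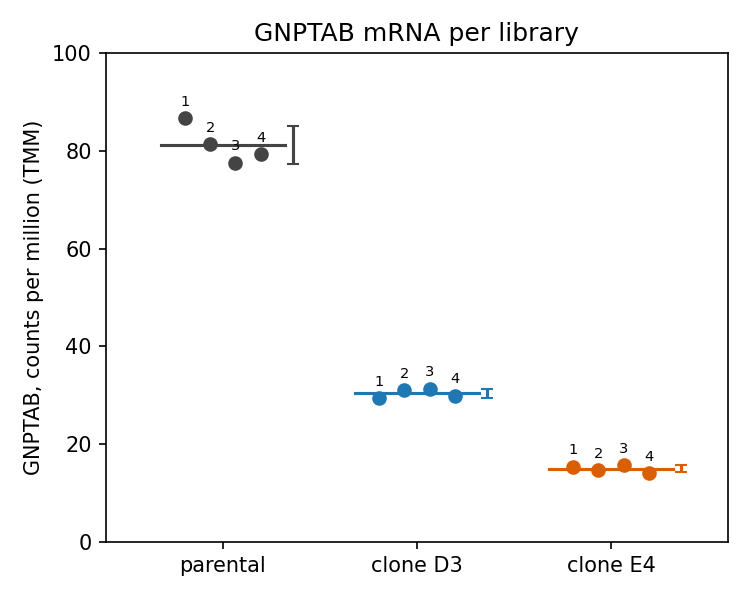
GNPTAB level in CPM in each of the 4 libraries of the parental line, clone D3 and clone E4, with the mean and SD of each line. The means were 81.2, 30.4 and 14.9 CPM, and the libraries of the lines did not overlap.

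The comparison of clone D3 with the parental line asks which genes differ in that clone. Genes of cholesterol synthesis, targets of the oxidative stress factor NRF2, and matrix proteases were higher, and collagen genes were among the largest falls. The lysosomal lists were higher as well, but their calls were lost with an estimated correlation (adjusted p = 0.055 for membrane and pump genes and 0.13 for soluble hydrolases with an estimated correlation). SPP1, which encodes the secreted matrix protein osteopontin, rose 11.4-fold, from 2.86 ± 0.319 to 32.7 ± 1.79 CPM (SD, n = 4), and MME, which encodes the peptidase neprilysin, rose 8.97-fold, from 10.2 ± 1.07 to 91.5 ± 2.82 CPM. NAA11, an N-terminal acetyltransferase, went from 16.8 ± 1.06 to 0.158 ± 0.0877 CPM, and COL23A1, a transmembrane collagen, from 39.6 ± 2.10 to 0.612 ± 0.207 CPM. In all, 10615 of 19270 genes were called (55.1%), 5365 higher and 5250 lower, of which 662 rose and 983 fell at least 2-fold.

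The other largest rises in clone D3 were TRIML2, with a log2 fold change of 3.77 ± 0.11, the potassium channel subunit KCNE4 (2.70 ± 0.14) and the secreted hormone stanniocalcin STC1 (2.60 ± 0.08). The other largest falls were the matrix genes MXRA5 (-3.54 ± 0.16), MGP (-3.28 ± 0.13) and COL3A1 (-2.71 ± 0.17). The adjusted p-values of these genes ran from 1.6e-21 for COL23A1 to 4.4e-12 for COL3A1. With scaling by library size alone, the median log2 fold change of all genes was -0.14 in place of -0.03, and 4016 genes were called higher and 7193 lower.

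Of the 25 genes of cholesterol synthesis and uptake, 21 rose in clone D3 and none fell, with a median log2 fold change of 0.90 (camera adjusted p = 1.5e-43, and 0.0021 with an estimated correlation). The sterol oxidase gene MSMO1 rose 3.55-fold, from 29.7 ± 0.917 to 106 ± 6.53 CPM (n = 4), and FDFT1, which encodes squalene synthase, 3.06-fold, from 113 ± 4.39 to 347 ± 20.4 CPM. FDFT1 lies on chromosome 8, whose genes had a median log2 fold change of 0.44 in this clone. Of 25 NRF2 targets, 23 rose and 1 fell, with a median of 0.62 (camera adjusted p = 5.8e-19, and 0.034 with an estimated correlation). They included the ferritin light chain FTL (267 ± 11.1 to 727 ± 45.4 CPM, 2.72-fold) and the haem oxygenase HMOX1 (1.89-fold). Of 31 matrix proteases and inhibitors, 20 rose and 3 fell, with a median of 0.58 (camera adjusted p = 2.3e-14, and 0.021 with an estimated correlation). The urokinase gene PLAU rose 3.32-fold, from 163 ± 8.28 to 543 ± 38.6 CPM, and the collagenase MMP1 3.33-fold. These 3 lists were the only calls of clone D3 that held with an estimated correlation.

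Lysosomal genes rose in clone D3 in both lists that describe them. Among 35 genes of the lysosomal membrane and proton pump, 28 rose and 4 fell (median 0.47; camera adjusted p = 4.2e-11; adjusted p = 0.055 with an estimated correlation), among them the sialic acid exporter SLC17A5 (1.18 ± 0.07) and the pump subunit ATP6V1B2 (1.17 ± 0.04, on chromosome 8), while LAPTM4A fell (-0.26 ± 0.04). Among 58 soluble hydrolases, the class of proteins that carries the mannose 6-phosphate tag, 30 rose and 7 fell (median 0.25; camera adjusted p = 4.0e-06; adjusted p = 0.13 with an estimated correlation). The cholesterol carrier NPC2 rose 2.26-fold and the sialidase NEU1 2.00-fold, while the collagen-degrading cathepsin CTSK (-1.14 ± 0.20) and the iduronidase IDUA (-0.77 ± 0.12) fell. Of 13 genes of mannose 6-phosphate tagging and sorting, 5 rose and 4 fell (camera adjusted p = 0.66). The tag receptor IGF2R rose 1.58-fold, the other tag receptor M6PR fell to 0.744-fold, GNPTG, the remaining subunit of the tagging enzyme, rose by 0.39 ± 0.07 (log2), and the uncovering enzyme NAGPA did not pass the test (0.02 ± 0.09). Of 31 autophagy genes, 12 rose, among them the cargo receptor SQSTM1 (2.17-fold), and 6 fell (camera adjusted p = 0.46).

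Of the stress and immune lists, NF-kB targets, stress responses, antigen presentation and p53 targets passed in clone D3, none of them with an estimated correlation, and the interferon response did not pass. Of 27 NF-kB and inflammatory targets, 19 rose and 5 fell (median 0.41; camera adjusted p = 1.9e-05; adjusted p = 0.42 with an estimated correlation), with the cytokine IL1A up 4.80-fold and TNF down to 0.400-fold. Of 25 genes of the unfolded protein and integrated stress responses, 19 rose and 2 fell (median 0.47; camera adjusted p = 0.0043; adjusted p = 0.42 with an estimated correlation). The 2 that fell were chaperones of the endoplasmic reticulum, HSP90B1 (-0.47 ± 0.04) and PDIA4 (-0.27 ± 0.04). Of 18 antigen presentation genes, 11 rose and none fell (median 0.25; camera adjusted p = 0.012; adjusted p = 0.50 with an estimated correlation), and B2M, the light chain of class I molecules, rose 1.45-fold. Of 23 p53 targets, 12 rose and 2 fell (camera adjusted p = 0.0099; adjusted p = 0.074 with an estimated correlation). Of 35 interferon response genes, 14 rose and 4 fell (camera adjusted p = 0.64), and the antiviral gene OASL was among the falls, from 54.9 ± 3.49 to 16.3 ± 3.82 CPM.

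Of 42 extracellular matrix genes, 17 rose and 21 fell in clone D3 (median -0.17; camera adjusted p = 0.0099; adjusted p = 0.42 with an estimated correlation). The collagen gene COL1A2 fell from 751 ± 35.8 to 159 ± 6.24 CPM, or 0.212-fold, while the laminin chains LAMA4 and LAMC1 rose 1.34-fold and 1.35-fold. Of 36 neuronal and synaptic genes, 9 rose and 14 fell (median -0.16; camera adjusted p = 0.012; adjusted p = 0.33 with an estimated correlation), with the synaptic vesicle protein SYP (-2.22 ± 0.20) and the adhesion molecule L1CAM (-1.91 ± 0.06) among the falls. With no filter beyond 1 count, the matrix and neuronal lists did not pass (adjusted p = 0.13 and 0.11). Of 45 neurodegeneration genes, 19 rose and 14 fell (median 0.05; camera adjusted p = 0.021; adjusted p = 0.27 with an estimated correlation). MME and the lipid carrier APOE (2.33-fold) rose, and the kinase CDK5 fell (0.680-fold); the list did not pass with scaling by library size alone (adjusted p = 0.15) or with the filter of 1 CPM in 4 libraries (adjusted p = 0.079).

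Genes of drug metabolism, the other interest of the series, moved in both directions in clone D3. Of 45 phase I enzymes, 13 rose and 11 fell (camera adjusted p = 0.66), with the aryl hydrocarbon receptor target CYP1A1 up 6.40-fold, from 0.868 ± 0.234 to 5.55 ± 0.557 CPM, and the quinone reductase NQO1 up 1.87-fold. Of 29 phase II enzymes, 9 rose and 8 fell (camera adjusted p = 0.34), and the glucuronosyltransferases UGT1A8 and UGT1A10 went from 5.85 ± 0.326 and 4.74 ± 0.483 CPM to 0.168 ± 0.138 and 0.185 ± 0.138 CPM. The UGT1A genes share exons, so the split of reads between them is uncertain. Of 26 drug transporters, 5 rose and 6 fell (camera adjusted p = 0.38).

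Markers of other cell types were tested beside these groups. Of 10 endothelial markers, 5 rose and 1 fell in clone D3 (median 0.53; camera adjusted p = 0.0047; adjusted p = 0.055 with an estimated correlation), and the receptor TEK rose 2.70-fold. Of 5 blood cell markers tested, 2 rose and 1 fell (camera adjusted p = 0.0099; adjusted p = 0.074 with an estimated correlation), with a median of -0.01, a mean of 0.41 and a rise in the test; the actin-bundling LCP1 rose 5.19-fold, and with no filter beyond 1 count the list did not pass (adjusted p = 0.48). Of 10 glial markers, 4 rose and 3 fell (camera adjusted p = 0.046; adjusted p = 0.17 with an estimated correlation), and the proteoglycan CSPG4 rose 3.45-fold. The glial call was lost (adjusted p = 0.052 to 0.087) when any parental or clone E4 library, or replicate 1 or 2 of clone D3, was left out. Of 15 epithelial markers, 1 rose and 6 fell (camera adjusted p = 0.36), and 12 of them fell in clone E4 with their lowest clone D3 value in replicate 3. Of the 10 hepatocyte markers, SERPINA1 alone had enough counts to be tested and rose 2.10-fold.

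In the lists of clone D3 that did not pass, 41 of 74 ribosomal protein genes rose and 16 fell (camera adjusted p = 0.080), and 16 of 34 cell cycle genes rose and 7 fell (0.093). In the sonic hedgehog pathway, active in a class of medulloblastoma, 5 of 17 genes rose and 8 fell (0.70), with CCND1 up 2.53-fold and the hedgehog-binding HHIP down to 0.242-fold. The counts risen and fallen were 9 and 9 of 26 in the TGF-beta list, 17 and 16 of 42 in glycosaminoglycan synthesis, 11 and 2 of 25 in sphingolipid synthesis, 25 and 19 of 77 in the nuclear-encoded respiratory chain, 5 and 2 of 13 in mitochondrial mRNAs, 13 and 7 of 34 in the proteasome and 4 and 5 of 18 in neural progenitor genes. They were 6 and 14 of 37 in HOX genes, 5 and 17 of 49 in clustered protocadherins, 8 and 6 of 19 in cancer-testis antigens and 6 and 6 of 19 in imprinted genes. Adjusted over the list alone, the counts were the same except for soluble hydrolases (31 and 7), blood cell markers (2 and 2), neuronal genes (9 and 16), protocadherins (4 and 17), phase II enzymes (10 and 8), phase I enzymes (12 and 10), drug transporters (4 and 6), epithelial markers (1 and 5), the proteasome (13 and 8), neural progenitor genes (4 and 4) and the cell cycle (17 and 7).

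Genes changed in clone D3 in long stretches of some chromosomes. On chromosome 8, all bins from 0 to 150 Mb were shifted upwards, with 436 of 682 genes higher, 34 lower and a median fold of 1.36. On chromosome 7 from 60 to 160 Mb, 413 of 657 genes were lower and 55 higher, with a median fold of 0.766. Chromosome 4 was lower from 20 to 50 Mb (median log2 fold change -0.38) and higher from 70 to 110 Mb (0.41) and from 120 to 190 Mb (0.30). Of 301 bins, 52 were shifted upwards and 42 downwards, and 33.7% of the called genes lay in them and moved in their direction. Shifted stretches of either clone are given beside some named genes only, and other named genes may lie in them as well.

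The comparison of clone E4 with the parental line asks the same of that clone. Cholesterol synthesis genes rose again, while interferon response, antigen presentation, epithelial and extracellular matrix genes fell. The calls of these 4 falling lists were lost with an estimated correlation (adjusted p = 0.38, 0.16, 0.18 and 0.16 with an estimated correlation), and markers of airway epithelium moved with the epithelial list. SEMA5A, an axon guidance protein, rose 14.1-fold, from 3.65 ± 0.375 to 51.5 ± 1.98 CPM (SD, n = 4), and MME rose 12.4-fold, from 10.2 ± 1.07 to 127 ± 8.19 CPM. HAPLN1, which links hyaluronan to proteoglycans, fell from 29.9 ± 1.73 to 1.63 ± 0.249 CPM, and VCAM1, a cell adhesion molecule of inflamed endothelium, from 15.3 ± 1.24 to 0.885 ± 0.220 CPM. In all, 10331 genes were called (53.6%), 5250 higher and 5081 lower, and 555 rose and 1190 fell at least 2-fold.

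The other largest rises in clone E4 were SPP1, with a log2 fold change of 3.37 ± 0.08, IGFN1 (3.36 ± 0.16) and the lysosomal and melanosomal glycoprotein GPNMB (2.72 ± 0.07). The other largest falls were LRRC61 (-3.80 ± 0.16), the adenylate cyclase ADCY1 (-3.60 ± 0.12) and COL3A1 (-3.20 ± 0.18). The adjusted p-values of these genes ran from 6.1e-22 for MME to 6.4e-13 for COL3A1. With scaling by library size alone, 4202 genes were called higher and 6244 lower.

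All 25 genes of cholesterol synthesis and uptake rose in clone E4, with a median log2 fold change of 1.08 (camera adjusted p = 1.5e-59, and 0.00048 with an estimated correlation); this was the only list call of clone E4 that held with an estimated correlation. MSMO1 rose 2.74-fold and FDFT1 2.55-fold. Of 25 NRF2 targets, 17 rose and 5 fell (median 0.28; camera adjusted p = 3.7e-09; adjusted p = 0.16 with an estimated correlation), with HMOX1 up 3.64-fold, FTL up 2.78-fold and the epoxide hydrolase EPHX1 down to 0.621-fold. Of 35 lysosomal membrane and pump genes, 27 rose and 4 fell (median 0.29; camera adjusted p = 4.0e-08; adjusted p = 0.16 with an estimated correlation). Of 58 soluble hydrolases, 25 rose and 17 fell (camera adjusted p = 0.072), with NPC2 up 1.92-fold and NEU1 up 1.94-fold. In the tagging and sorting list 7 genes rose and 2 fell (camera adjusted p = 0.64): IGF2R (1.72-fold), M6PR (1.36-fold) and the sorting receptor SORT1 (1.41-fold) rose, and the protease MBTPS1, which activates the tagging enzyme, fell (-0.14 ± 0.04). Of 31 autophagy genes, 15 rose and 3 fell (median 0.12; camera adjusted p = 0.020; adjusted p = 0.38 with an estimated correlation), with WIPI1 up 2.71-fold; with the 10 Mb bin medians taken off, chosen after the data were seen, the list did not pass (adjusted p = 0.081).

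Interferon response genes fell in clone E4: 29 of 35 were lower and 2 higher, with a median of -1.05 (camera adjusted p = 7.3e-09; adjusted p = 0.38 with an estimated correlation). OASL fell to 0.115-fold, from 54.9 ± 3.49 to 6.30 ± 1.12 CPM (n = 4), and XAF1 to 0.339-fold. None of the 35 was among the 170 genes that were lower by at least 0.5 (log2) in replicate 3 of clone D3 and passed the edgeR test of that library against the others of its clone, although IFI27 had its lowest level of that clone there. IFI27, picked after its values were seen, was at 1.17 and 1.06 CPM in replicates 1 and 2 of clone E4 and at 6.96 and 7.19 CPM in replicates 3 and 4. The same pairs stood at 10.5 and 10.8 against 20.8 and 24.6 CPM in the parental line and at 23.5 and 28.2 against 9.64 and 10.5 CPM in clone D3. Of 18 antigen presentation genes, 17 fell (median -0.57; camera adjusted p = 1.1e-08; adjusted p = 0.16 with an estimated correlation), with CD74 at 0.335-fold, while B2M did not pass the test (-0.02 ± 0.04). CD74 was also low in replicate 3 of clone D3, at 8.25 CPM against 28.4, 29.4 and 14.2 CPM in replicates 1, 2 and 4. In a step chosen after the data were seen, the part of each level that follows the airway secretory genes BPIFA1 and BPIFB1 was taken off. BPIFA1 and BPIFB1 accounted for 82.5% of the variance within lines at the median of the fallen interferon genes. This share was 40.4% for antigen presentation and 81.5% for epithelial markers. After that step, 13 of the 29 fallen interferon genes and 12 of the 17 fallen antigen presentation genes still passed as lower. The part taken off was 29.3% and 6.16% of the parental level at the median. For CD74 it was 106%, which left a difference of 0.0626 ± 2.60 CPM (SE). The levels left were negative, at -1.51 CPM in the parental line and -1.45 CPM in clone E4, so that difference does not measure a fall. Of 27 NF-kB targets, 7 rose and 11 fell (camera adjusted p = 0.31), with TNF at 0.0728-fold and IL1A at 2.05-fold. Of 25 stress response genes, 7 rose and 15 fell (median -0.31; camera adjusted p = 0.013; adjusted p = 0.50 with an estimated correlation), although EDEM1 and PPP1R15A rose 1.48-fold and 1.33-fold.

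All 15 epithelial markers fell in clone E4, with a median of -1.48 (camera adjusted p = 3.7e-09; adjusted p = 0.18 with an estimated correlation). KRT5, a keratin of basal epithelial cells, went from 167 ± 13.8 to 57.7 ± 4.53 CPM (n = 4), KRT8 from 379 ± 11.2 to 209 ± 2.38 CPM and KRT18 from 712 ± 19.1 to 456 ± 12.9 CPM. Genes of airway epithelium, listed after the data were seen, moved with them. Of 52 airway markers tested outside the list, 51 fell in clone E4 (median -1.38), and 50 fell and were also lowest in replicate 3 among the libraries of clone D3, as did 8.37% of all genes. The cilium regulator FOXJ1 was at 20.8, 17.6 and 6.53 CPM in the parental line, clone D3 and clone E4, and at 6.94 CPM in replicate 3 of clone D3. After the part that follows BPIFA1 and BPIFB1 was taken off, 5 of the 15 epithelial markers still passed as lower, and that part was 72% of the parental level at the median. The 170 genes that stood low in replicate 3 of clone D3 made up 144 (12.1%) of the 1190 falls of at least 2-fold in clone E4, 7 of the 15 epithelial markers, and 5 of the 23 phase I enzymes that fell. KRT5, KRT7, KRT8 and KRT18 also lie in a stretch of chromosome 12 that was lower in this clone.

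**Figure D2:**
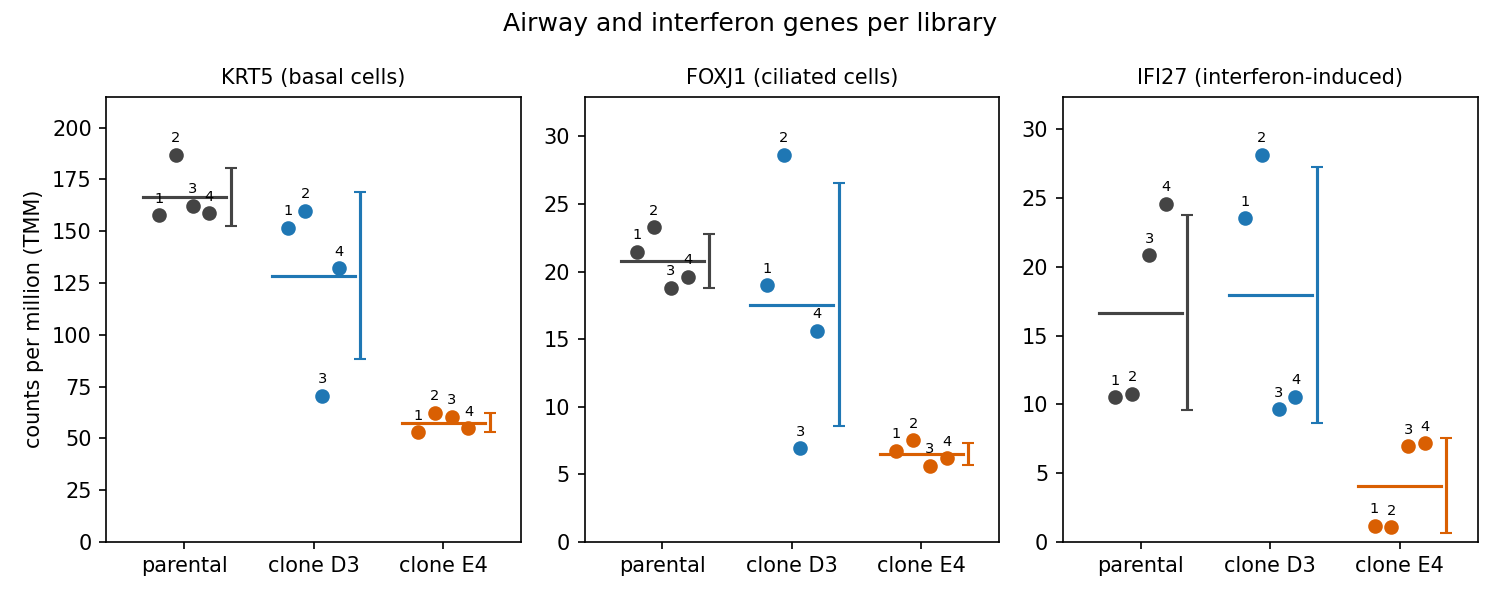
Levels in CPM of KRT5, FOXJ1 and IFI27 in each library of the 3 lines, with the mean and SD of each line. KRT5 and FOXJ1 were low in all libraries of clone E4 and in replicate 3 of clone D3, whereas IFI27 differed between replicates 1 and 2 and replicates 3 and 4 within each line.

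Of 42 extracellular matrix genes, 26 fell and 8 rose in clone E4 (median -0.38; camera adjusted p = 9.0e-10; adjusted p = 0.16 with an estimated correlation). COL1A2 fell to 0.263-fold and the small proteoglycan BGN to 0.139-fold, while LAMA4 rose 1.59-fold. Of 74 cytosolic ribosomal protein genes, 36 fell and 3 rose (median -0.09; camera adjusted p = 0.00049; adjusted p = 0.70 with an estimated correlation), with RPL37 at 0.635-fold. Of 45 neurodegeneration genes, 24 rose and 9 fell (median 0.14; camera adjusted p = 0.0034; adjusted p = 0.16 with an estimated correlation), MME the most and APOE 1.56-fold. Of 19 cancer-testis antigens, 12 rose and 5 fell (median 0.23; camera adjusted p = 0.0036; adjusted p = 0.38 with an estimated correlation), with MAGEB2 up 2.35-fold; members of such families share sequence, and with the bin medians taken off the list did not pass (adjusted p = 0.21). Of 23 p53 targets, 4 rose and 9 fell (median -0.11; camera adjusted p = 0.038; adjusted p = 0.16 with an estimated correlation), which was lost without replicate 1 of clone E4 (adjusted p = 0.058), without the genes apart in replicate 3 of clone D3 (0.052) and with the bin medians taken off (0.058).

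None of the drug metabolism lists passed in clone E4. Of 45 phase I enzymes, 9 rose and 23 fell (camera adjusted p = 0.13), with CYP1A1 up 1.73-fold and NQO1 up 1.48-fold. Of 29 phase II enzymes, 11 rose and 15 fell (0.53), with UGT1A10 at 0.0419-fold and UGT1A8 at 0.273-fold. Of 26 drug transporters, 7 rose and 10 fell (0.48), with the prostaglandin carrier SLCO2A1 at 0.684-fold. Of 36 neuronal genes, 8 rose and 10 fell (0.75), with the neuronal enolase ENO2 up 2.49-fold, and L1CAM and SYP down to 0.545-fold and 0.448-fold. Of 18 neural progenitor genes, 7 rose and 6 fell (0.97), among the latter SOX4 (-0.35 ± 0.04) and PROM1 (-1.12 ± 0.18), which was also low in replicate 3 of clone D3. In the sonic hedgehog pathway 5 of 17 genes rose, GLI2 by 2.10-fold, and 3 fell, HHIP to 0.213-fold (0.28).

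In the other lists of clone E4, none of which passed, the counts risen and fallen were 13 and 11 of 31 for matrix proteases (camera adjusted p = 0.13), 2 and 5 of 10 for endothelial markers (0.21), 5 and 0 of 13 for mitochondrial mRNAs (0.20), 4 and 10 of 19 for imprinted genes (0.16), 19 and 6 of 34 for the proteasome (0.32) and 14 and 7 of 34 for the cell cycle (0.41). They were 13 and 17 of 42 for glycosaminoglycan synthesis, 27 and 17 of 77 for the respiratory chain, 8 and 10 of 25 for sphingolipid synthesis, 6 and 10 of 26 for the TGF-beta list, 10 and 11 of 37 for HOX genes, 12 and 13 of 49 for protocadherins, 1 and 2 of 5 for blood cell markers and 3 and 4 of 10 for glial markers. Of the HOX genes, 9, all of the HOXC cluster, lie in the stretch of chromosome 12 that was lower. Adjusted over the list alone, the counts were the same except for phase I enzymes (9 and 25), neurodegeneration genes (25 and 9), the sonic hedgehog pathway (6 and 4), imprinted genes (5 and 10), blood cell markers (1 and 3) and endothelial markers (2 and 6).

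The stretch of chromosome 12 with lower expression in clone E4 ran from ALG10B (start 38316578) to CHPT1 (end 101744140), the last gene scanned before GNPTAB. Its 279 genes of the 629 scanned had a median log2 fold change of -0.53 against 0.19 elsewhere on the chromosome, a ratio of 0.606. None of 1000 shuffles of gene order gave as large a statistic (permutation p = 0.001, the smallest they can give), and it was the largest of the scans of 23 chromosomes in each clone. The next gene, DRAM1, starts 46.7 kb beyond the guide's target site, and CHPT1 ends 86.5 kb before it. Within 10 Mb of the target site, none of 32 genes on the centromere side was higher and 29 were lower, while 34 of 65 on the telomere side were higher and 9 lower. In clone D3 the medians of the same genes were -0.12 and -0.14. Besides the keratins and HOXC genes, the stretch holds RPS26, NDUFA12, ATP5MC2, B4GALNT1, STAT2 and DDIT3 of the gene lists. Chromosome 12 was higher in clone E4 from 0 to 30 Mb (0.24), as were chromosome 2 from 50 to 120 Mb (0.31) and chromosome 6 from 140 to 170 Mb (0.38). Of 301 bins, 59 were shifted upwards and 42 downwards, and 36.6% of the called genes lay in them and moved in their direction.

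**Figure D3:**
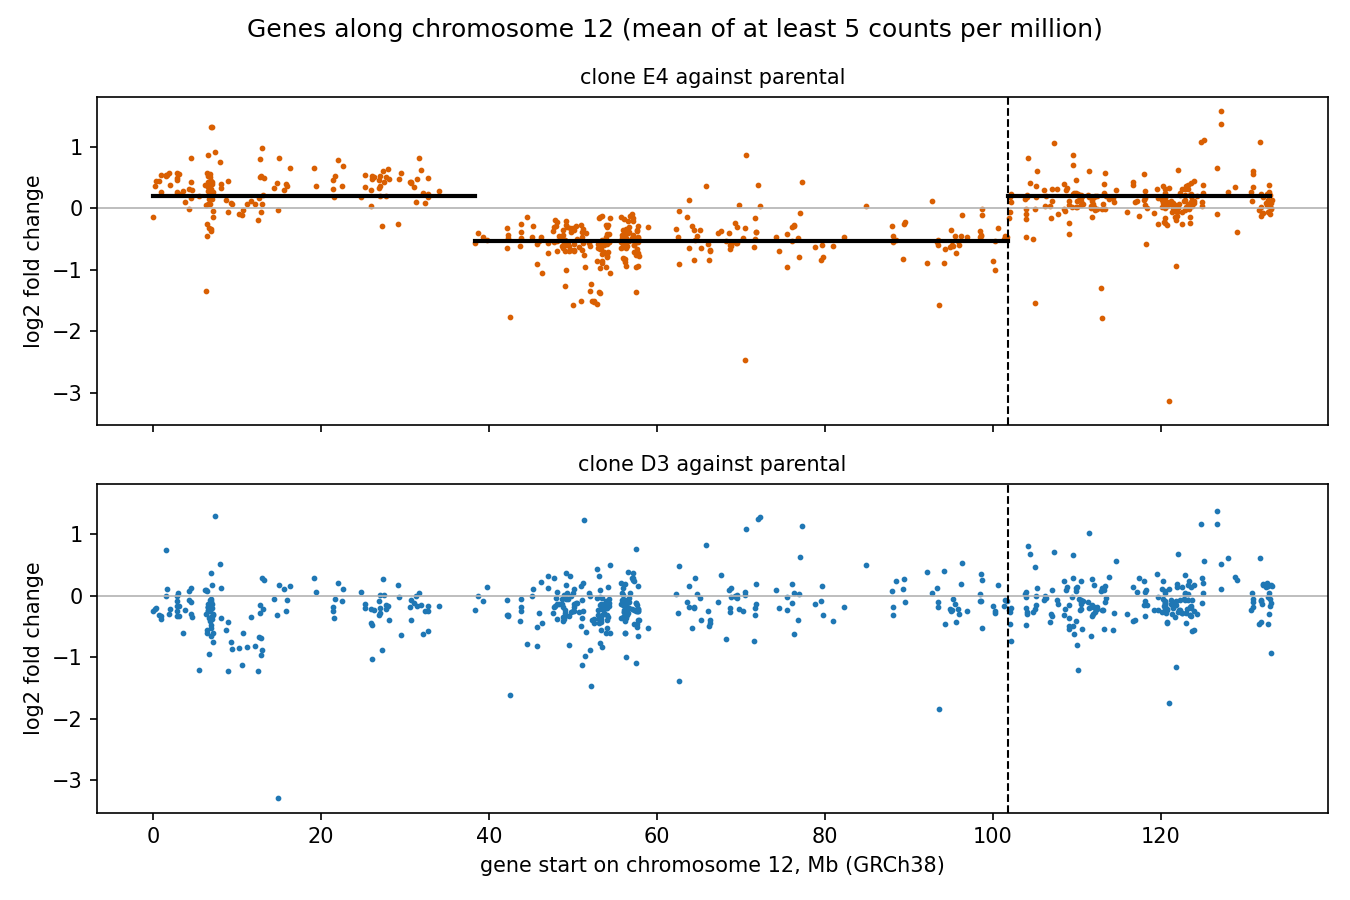
Log2 fold change against the parental line of each scanned gene along chromosome 12 (position in Mb) in clone E4 and clone D3; the dashed line marks the guide's target site and the black lines the medians of the stretches. In clone E4 the median was -0.53 within the stretch and 0.19 outside it.

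The overlap of both comparisons asks what the clones share. The libraries include no clone with unedited GNPTAB. Editing of GNPTAB and the making of a clone therefore cannot be told apart as causes of a shared change. Cholesterol synthesis, NRF2 targets and lysosomal membrane genes rose in both, and COL3A1, COL1A2 and BGN fell in both. Of these lists only cholesterol synthesis held in both clones with an estimated correlation; in clones D3 and E4, NRF2 targets gave adjusted p = 0.034 and 0.16 and lysosomal membrane genes adjusted p = 0.055 and 0.16 with an estimated correlation. The shared rises with the largest smaller change were SPP1, MME, STC1, TRIML2, GPNMB, the activin antagonist FST (3.83-fold and 6.44-fold in clones D3 and E4), the sialic acid receptor SIGLEC15 (4.51-fold and 5.98-fold) and SPANXB1, one of a family of nearly identical genes (5.34-fold and 4.56-fold). GPNMB went from 45.6 ± 6.84 CPM (SD, n = 4) to 210 ± 8.77 and 301 ± 4.81 CPM. The shared falls included COL3A1, COL1A2, HHIP, BGN, OASL, the planar polarity gene PRICKLE1 (0.324-fold and 0.294-fold) and the cytokine signalling inhibitor SOCS2 (0.280-fold and 0.336-fold); PRICKLE1 and SOCS2 lie in the lower stretch of chromosome 12 of clone E4. POSTN, a matrix protein, was at 1.58 ± 0.0941 CPM in the parental line and at 0.0369 ± 0.0299 and 0.0667 ± 0.0519 CPM in the clones.

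In all, 2728 genes rose and 2238 fell in both clones, where independent lists would share 1462 and 1384, and 1640 moved in opposite directions, where 2845 were expected. With scaling by library size alone, 1871 rose and 3380 fell in both, so the share that rose went from 54.9% to 35.6%. Among changes of at least 2-fold, 230 rose and 207 fell in both, against 19 and 61 of independent lists. In 20 simulations with unchanged clones and shared parental libraries, no gene rose and at most 1 fell in both. Only 0.75 and 0.6 genes on average were called in the simulated clones D3 and E4. These overlaps therefore cannot show what shared libraries add when each clone has many changes. With different parental libraries for each clone, 2 in place of 4, 2161 to 2311 genes rose and 1453 to 1551 fell in both. Across genes, the log2 fold changes of the clones correlated with r = 0.372 (jackknife error 0.0417), and with r = 0.306 to 0.322 with different parental libraries. Shared controls alone gave r = 0.473 to 0.537 in the simulations, a range above the observed value. The simulated fold changes held noise only, so that range does not measure what shared libraries add to the observed r. The covariance of the clones was 0.154, against 0.0186 in the simulations.

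**Figure D4:**
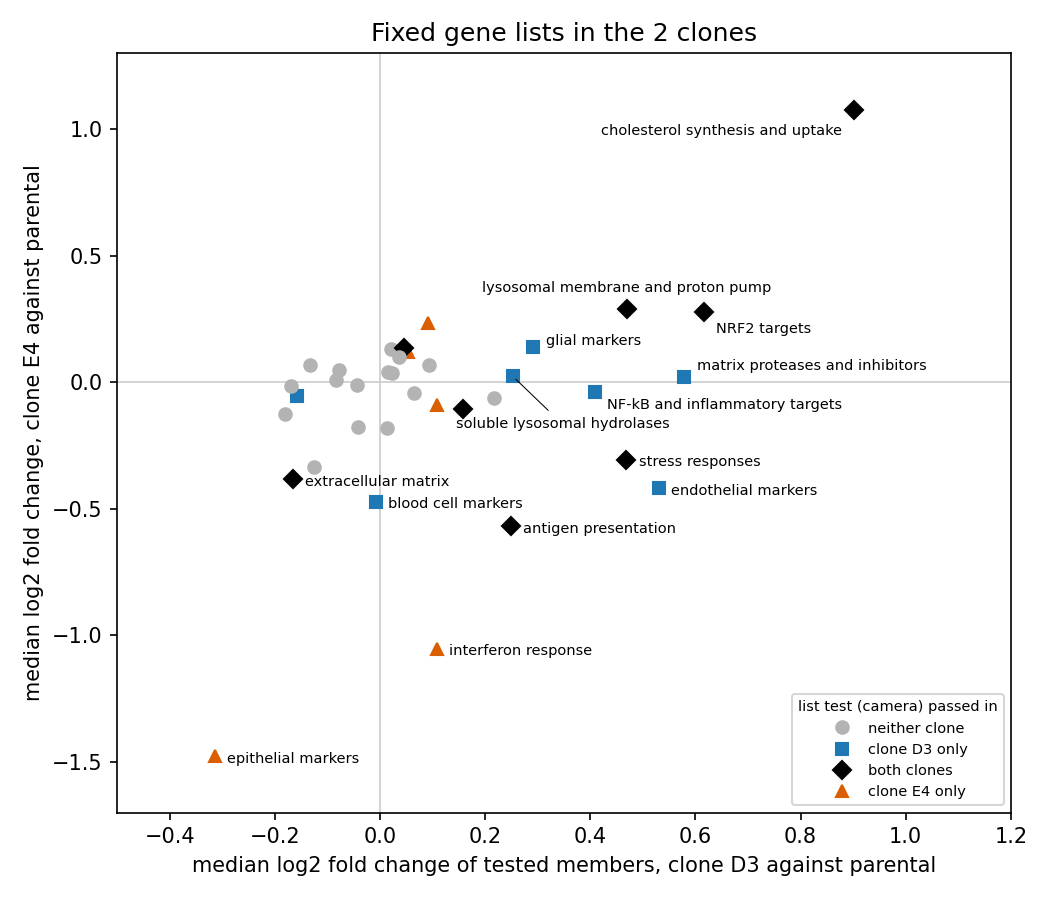
Median log2 fold change of the tested members of each gene list in clone D3 (horizontal) and clone E4 (vertical), marked by whether camera with the preset correlation passed in neither, either or both clones. Cholesterol synthesis and uptake is highest in both clones (0.90 and 1.08), and epithelial markers are lowest in clone E4 (-1.48).

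The direct comparison of clone E4 with clone D3 asks where the clones differ, and the parental level cancels in it. Antigen presentation, interferon, NF-kB, stress response, p53 and ribosomal protein genes were lower in clone E4 than in clone D3, while cholesterol synthesis did not pass the test as a list. Of these 6 lower lists, only p53 targets held with an estimated correlation (adjusted p = 0.016), and the others gave adjusted p = 0.055, 0.35, 0.35, 0.18 and 0.49 with an estimated correlation. ADCY1 rose from 8.07 ± 0.689 to 23.9 ± 0.725 CPM (SD, n = 4) in clone D3 and fell to 0.659 ± 0.0468 CPM in clone E4. THBS2, a secreted matrix glycoprotein, went the other way, from 111 ± 1.86 to 33.9 ± 4.17 and 485 ± 9.04 CPM. In all, 11114 genes differed (57.7%), 5506 higher and 5608 lower in clone E4.

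The other genes that moved oppositely were higher in clone D3 for the stress-induced cytokine GDF15 (3.26-fold in clone D3 and 0.356-fold in clone E4), the glutathione-degrading CHAC1 (2.34-fold and 0.143-fold) and the gelatinase MMP9 (2.47-fold and 0.459-fold). They were higher in clone E4 for the neuropeptide precursor SCG2 (0.336-fold and 3.78-fold), LYPD6B (0.349-fold and 2.82-fold) and SEMA5A (0.450-fold and 14.1-fold). The log2 differences of the 8 genes ran from -5.17 (ADCY1, adjusted p = 7.2e-21) to 4.96 (SEMA5A, adjusted p = 6.6e-23).

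Of 18 antigen presentation genes, 17 were lower in clone E4 than in clone D3 (median -0.80; camera adjusted p = 8.2e-15; adjusted p = 0.055 with an estimated correlation). So were 29 of 35 interferon genes (median -1.10; camera adjusted p = 5.7e-09; adjusted p = 0.35 with an estimated correlation), 20 of 27 NF-kB targets (-0.71; 4.0e-08; adjusted p = 0.35 with an estimated correlation), 19 of 25 stress response genes (-0.57; 5.6e-08; adjusted p = 0.18 with an estimated correlation) and 19 of 31 matrix proteases (-0.42; 1.5e-08; adjusted p = 0.055 with an estimated correlation). Of 23 p53 targets 16 were lower (-0.54; camera adjusted p = 1.3e-06, and 0.016 with an estimated correlation), and of 10 endothelial markers 5 were lower and 1 higher (-0.35; 2.7e-05, and 0.019 with an estimated correlation). TEK and TIE1, receptors of endothelial cells, rose 2.70-fold and 2.10-fold in clone D3 and fell to 0.528-fold and 0.585-fold in clone E4. These 2 lists were the only calls of this comparison that held with an estimated correlation.

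Lower in clone E4 were also 53 of 74 ribosomal protein genes (-0.21; camera adjusted p = 1.5e-07; adjusted p = 0.49 with an estimated correlation), all 15 epithelial markers (-1.20; 2.9e-05), 15 of 25 NRF2 targets (-0.34; 0.0026), 32 of 58 soluble hydrolases (-0.21; 0.0091) and 21 of 42 extracellular matrix genes (-0.21; 0.0091), each of the last 4 with adjusted p = 0.35 with an estimated correlation. The airway markers moved with the epithelial list here too, with a median of -1.38 in clone E4 and -0.35 in clone D3 against the parental line, and 6 phase I enzymes and 1 antigen presentation gene were among the genes low in replicate 3 of clone D3. Glial markers (6 of 10 lower; camera adjusted p = 0.016; adjusted p = 0.18 with an estimated correlation), sphingolipid genes (11 of 25 lower; 0.046; adjusted p = 0.35 with an estimated correlation) and phase I enzymes (25 of 45 lower; 0.048; adjusted p = 0.57 with an estimated correlation) passed as well. Neuronal genes were higher in clone E4 (14 of 36 higher and 8 lower; 0.037; adjusted p = 0.35 with an estimated correlation). The last 3 calls, of sphingolipid, phase I and neuronal genes, were lost when some libraries were left out: sphingolipid genes gave adjusted p = 0.051 to 0.062 without parental replicate 2, replicates 1 or 4 of clone D3 or replicates 1 or 4 of clone E4, phase I enzymes 0.055 to 0.082 without parental replicate 3, replicates 1, 2 or 4 of clone D3 or replicates 1 or 3 of clone E4, and neuronal genes 0.055 to 0.065 without replicates 1, 2 or 4 of clone D3. Neuronal genes, the only list that passed as higher in clone E4, also did not pass with scaling by library size alone (adjusted p = 0.050) or with no filter beyond 1 count (0.17), nor did sphingolipid genes with library size alone (0.054) or the filter of 1 CPM in 4 libraries (0.059). Without the genes apart in replicate 3 of clone D3, phase I enzymes (0.11) and sphingolipid genes (0.057) did not pass. Cholesterol genes (13 of 25 higher and 6 lower; 0.41) and lysosomal membrane genes (9 of 35 higher and 19 lower; 0.19) did not pass. Adjusted over the list alone, the counts were the same except for lysosomal membrane genes (10 and 20), extracellular matrix (12 and 22), matrix proteases (7 and 19), interferon genes (0 and 30), antigen presentation (0 and 18), NF-kB targets (3 and 21) and ribosomal proteins (12 and 56), each given as higher and lower in clone E4; of the lists not named here, 4 differed by at most 2 genes.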

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

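The tests of airway epithelial signal below were chosen only after the result was seen; the tests on other splits of the libraries and on chromosome segments were planned.

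The 15 epithelial markers and 29 of 35 interferon response genes were lower in clone E4, and RNA or reads of airway epithelial cells mixed into the libraries is a candidate explanation for the former. Outside that list, 52 markers of ciliated, secretory and basal airway cells were tested. Of these, 96.2% fell in clone E4 and were lowest in replicate 3 of clone D3, against 8.37% of all genes. The abundant secretory gene BPIFB1 was at 71.7 CPM in the parental line, 24.8 CPM in clone E4 and 23.2 CPM in that replicate. For the interferon genes below, airway signal means only the part of each level that follows BPIFA1 and BPIFB1. The tables argue against 1 source with a fixed profile, since the ratio of BPIFA1 to BPIFB1 counts differed 3.03-fold between libraries (0.426 to 0.528 in replicates 1 and 2 against 0.897 to 1.29 in replicates 3 and 4 of the parental line and clone E4, but 0.955 and 0.666 against 0.635 and 0.603 in clone D3; the labels give no library sets, and sources that differ between sets stay open), and against the airway signal as the whole cause of the interferon falls: once the part following BPIFA1 and BPIFB1 was taken off, 44.8% of the fallen genes still passed as lower, while the other 16 lost the call on 7 residual degrees of freedom, from OAS1, at 10.5 and 4.26 CPM in the parental line and clone E4 before and 3.55 and 1.42 CPM after (difference -2.14 ± 1.36 CPM, SE), to IFI27, IFI6, CMPK2 and IRF7, picked after their values were seen, which kept no fall (0.419 ± 3.98, 0.0778 ± 5.23, 0.300 ± 1.12 and -0.00296 ± 0.602 CPM) and for which the airway signal stays open. Lower epithelial expression in clone E4 itself and the airway signal cannot be told apart for the list: after that step 5 markers (KRT5, KRT8, KRT14, KRT18 and ESRP2) still passed as lower, and 8 of the other 10 were lower without passing, from KRT7, at 20.6 and 7.29 CPM before and 5.14 and 1.70 CPM after (difference -3.45 ± 1.57 CPM, SE), to KRT19, at 158 and 52.7 CPM before and 4.95 and 0.210 CPM after (-4.74 ± 10.2 CPM), while the part taken off was 72% of the parental level at the median of the list. KRT5, KRT8 and KRT18 lie in the lower stretch of chromosome 12, and the knockout stays open and untested as a cause. Airway RNA that does not follow BPIFA1 and BPIFB1 was not taken off by that step. As a cause it stays open for all 29 fallen interferon genes. The genes retested were also those already called as fallen in the same comparison, which favours calls that survive.

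Gains and losses of chromosome segments in the clones were weighed as the source of most calls. If they were, over 50% of called genes would lie in shifted 10 Mb bins and move with them; the shares were 33.7% in clone D3 and 36.6% in clone E4. Outside shifted bins 51.7% and 50.1% of genes were called. Shifted bins held only 6916 genes in clone D3 and 7835 in clone E4, which made a share of 50% hard to reach. Smaller shifts in other bins would also be missed. The segments may contribute to the calls within them. The test does not settle how much, and they stay open there and outside shifted bins, since copy number was not measured.

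The group labels mattered for each count of genes. In clone D3, 1 of the 35 splits of its 8 libraries, the real one, called 10615 genes with edgeR, and the highest of the others called 0 at an adjusted p under 0.05. In clone E4 it was again 1 of 35, with 10331 genes and a highest other of 0, and between the clones 1 of 35, with 11114 genes and 0. For genes changed alike in both clones it was 1 of 100, with 4966 and 0. For gene lists it was 1 of 35 each: 15 against at most 14 in clone D3, 13 against at most 12 in clone E4 and 16 against at most 14 between the clones. Every other split mixed libraries of different lines, which widens the spread within its groups. Counts of 0 there show that the real grouping stands out, but not how many genes would differ by chance between clones or cultures. For the lists the real split led by only 1 or 2. Leaving out 1 library gave as few as 14, 12 and 13 lists, no more than the highest other split. The real grouping is therefore not said to stand out for the lists.

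The effects of the clones differed in 11114 genes, 16 gene lists and 139 of the 196 named genes, each by the direct test of clone E4 against clone D3. In 8 named genes they were opposite, with log2 differences of -5.17 (ADCY1), -3.195 (GDF15), -4.03 (CHAC1), -2.43 (MMP9), 3.84 (THBS2), 3.49 (SCG2), 3.02 (LYPD6B) and 4.965 (SEMA5A).

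Of 600 groups of 4 libraries checked, 31 held a library apart from the other 3 by Dixon's 95% criterion; chance flags about 1 in 20. The gap over the group's range was, in the parental line, 0.867 for MME, 0.865 for VCAM1, 0.890 for CHAC1, 0.885 for M6PR, 0.840 for SLC17A5, 0.902 for PSMD11, 0.946 for PAGE1, 0.846 for KRT5, 0.902 for CDH1 and 0.855 for OVOL1. In clone D3 they were 0.863 for OASL, 0.960 for CHAC1, 0.864 for CSPG4, 0.977 for ACTA2, 0.897 for SP100, 0.835 for RPL31, 0.862 for HOXB7, 0.887 for PCDHGB1, 1 for CTAG2, which had counts in only 1 library of that clone, and 0.910 for EPCAM, whose low library was replicate 3. In clone E4 they were 0.889 for M6PR, 0.895 for AP1G1, 0.869 for HSP90B1, 0.862 for PSMD11, 0.852 for ZIC2, 0.995 for CCL20, 0.929 for PCDHA10, 0.846 for MAGEB1, 0.838 for KRT18, 0.939 for KRT8 and 0.831 for CSF1R.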

How the results depend on the processing

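The tests without the genes apart in replicate 3 of clone D3 and with the 10 Mb bin medians as an offset were chosen only after the results were seen; the others were planned. Neither the called named genes and lists nor the correlation changed sign under the alternatives run for them, but the larger direction of the gene counts did not hold. With scaling by library size alone 4016 genes rose and 7193 fell in clone D3, 4202 and 6244 in clone E4 and 1871 and 3380 alike in both clones, where falls had been fewer, and 6130 and 5132 between the clones, where they had been more; counts near balance also turned under other alternatives. Of the values of the counts, the correlation and GNPTAB, 210 were within the set limits and 17 moved. Tested against changes of up to 1.5-fold, 1736 genes were called in clone D3 (898 higher, 838 lower), 1679 in clone E4 (629 and 1050), 1891 between the clones (831 and 1060) and 466 alike in both clones; the higher bar shows the cause. The correlation of the clones was 0.463 without a filter, where the cause was not tested, and 0.308, 0.318, 0.321, 0.316, 0.322 and 0.306 with different parental libraries for each clone, which takes off the shared term and also leaves 2 parental libraries per clone, and so more noise; the parts were not separated. With an estimated correlation 3 lists were called in clone D3, 1 in clone E4 and 2 between the clones, and with fry, which does not compare a list with other genes, 28, 24 and 29. Leaving out each library in turn gave 9975 to 10705 genes in clone D3, 9528 to 10573 in clone E4, 10453 to 11247 between the clones and 4445 to 4991 alike in both. With a block for replicate number the counts were 10488, 10111, 10923 and 4858; the numbers did not pair libraries, since 3 of 12 correlations between libraries of the same number exceeded 0.1. Without the genes apart in replicate 3 of clone D3 the counts were 10660, 10227, 10991 and 4981, and the calls of glial markers in clone D3, p53 targets in clone E4 and phase I and sphingolipid genes between the clones were lost. With the bin medians taken off they were 9360 in clone D3, 8807 in clone E4 and 4376 alike in both, and the calls of glial markers in clone D3 and autophagy, p53 and cancer-testis lists in clone E4 were lost. Of the values of named genes, 7282 kept their direction and side of the threshold and 393 kept their direction and lost the call. Of those of lists, 825 and 82 did. Of the list calls lost, 5 were lost with no filter beyond 1 count and 3 with the filter of 1 CPM in 4 libraries. In simulated data with the depth and spread of these libraries, 44.9% and 36.0% of changes of 1.25-fold were found. Whether depth or spread limits small changes was not tested. Far fewer genes were changed in those data than were called here, which makes the adjustment stricter there. These shares therefore need not hold for the real libraries.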

Other observations

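The test of the chromosome 12 segment below was chosen only after the result was seen. Smaller gene groups hold further changes shared by both clones. The mitochondrial mRNA of MT-ND1 rose 1.35-fold in clone D3 and 1.41-fold in clone E4, and the nuclear CYC1, a cytochrome of complex III, 1.96-fold and 1.21-fold, the former on the raised chromosome 8. The imprinted MEST, a gene expressed from the paternal copy, fell to 0.514-fold and 0.692-fold, and PHLDA2 rose 1.72-fold and 1.35-fold. CSGALNACT1, which starts chondroitin chains, fell to 0.250-fold and 0.441-fold of the parental level, and the hyaluronan synthase HAS2 to 0.520-fold and 0.389-fold, while EXTL3 rose 1.83-fold and 1.25-fold. In the TGF-beta list the receptor TGFBR2 rose 2.57-fold and 1.43-fold and the target ID2 1.28-fold and 1.94-fold, while the smooth muscle actin ACTA2 fell to 0.701-fold and 0.436-fold and SNAI1 to 0.667-fold and 0.660-fold. Among cell cycle genes the replication licensing factors MCM2 and MCM7 fell to 0.799-fold and 0.867-fold in clone D3 and to 0.856-fold and 0.895-fold in clone E4, while CDC6 rose 1.37-fold and 1.44-fold. HOXB2 rose 1.40-fold and 1.48-fold. The proteasome subunit PSMD12 rose 1.26-fold and 1.28-fold, and the ceramide desaturase DEGS1 1.31-fold and 1.37-fold. Among these genes only CYC1 is set against the shifted chromosome stretches here, and others may lie in them as well.

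Loss of part of chromosome 12 from the guide's target site towards the centromere in some or all cells of clone E4 is a hypothesis for its lower expression there. The scan, which left GNPTAB out, placed the end of the segment at CHPT1, 86.5 kb from the target site, where an edge over 10000 kb away would have argued against it. The next best edge lay before WASHC3, the first gene beyond it, also near the site. The ratio of 0.606 inside to outside the segment lies near the 0.667 that loss of 1 of 3 copies would give. The medians of clone D3 on both sides of the site were alike (-0.12 and -0.14). DNA copy number was not analysed here, so an unrelated break at the same place, or a copy number of the parental line that differs between its cells, stays open.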
